A study of Homo sapiens with 6 samples.

How the data were processed

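Translation complex profiling measures the RNA protected by ribosomal complexes. Per the labels' protocols, HEK293T cells were grown for 48 h at 37 °C, fixed with 0.3% formaldehyde for 5 min, lysed and treated with RNase I, and 40S and 80S fractions were separated, with a further pull-down against eIF3b for 1 library. Per the labels, the number 1 libraries had been sequenced as paired ends with only read 1 used, so the library number goes with the read layout. Per the submitters' processing notes, CASAVA 1.8, Bowtie 1.2.2, Bowtie2 2.2.6 and TopHat2 2.1.0 were used with genome build GRCh38. The role of each tool, the use of strand and the rule for reads that match several genes are not given in the sources used here.

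The deposited table of footprint counts gives, per the file headers, a whole-number count per gene in 5 areas (5′ UTR, start codon, coding sequence, stop codon, 3′ UTR) for the eIF3b-bound library and 40S 1. The deposited metagene files hold whole-number counts of footprint 5′ ends from 80 nt before to 30 nt after start and stop codons in 81 columns of footprint length, for both 40S and both 80S libraries. Those length columns carry no header. A first length of 18 nt gave the best match with the separately deposited 3′ ends (Pearson correlation across positions 0.996 in 40S 1 and 0.997 in 40S 2), was used for all 4 libraries, and could not be checked for 80S. The authors also deposited, as a fraction of each gene's footprint ends averaged over genes with a 95 percentile interval, means per position around the start codon for both 40S libraries. Their 5′ ends lie at -14 to -12 only. Coverage (signal) per position and library was deposited, as whole numbers with no sign of scaling for depth, for transcript 5′ ends and for the ATF4 transcript. The ATF4 file begins 50 nt before the annotated 5′ end, and positions are given from that end. No column was left unmapped (0).

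Counts were summed over areas per gene. The ratio of the eIF3b-bound library to 40S 1 was taken as log2 of CPM with a prior count of 0.5, for genes with at least 20 counts in both libraries together, which kept 4175 of 9675 genes; 3381 had no count in either library. The design had set the eIF3b-bound library against the mean of both 40S libraries, but gene counts of 40S 2, of 80S and of mRNA were not used here. The planned edgeR quasi-likelihood tests of 80S against 40S per gene and area, the list tests between them and ribosome load per mRNA were therefore not run. Libraries without a replicate were compared without a test. Exact Clopper-Pearson intervals at 95% (scipy 1.17.1) describe counting error only, since reads without molecular identifiers are not independent molecules. Of the gene identifiers, 8322 matched a symbol and 1353 did not; the latter held 5.57% of the 40S 1 counts and 1.70% of the eIF3b-bound counts. Coordinates come from the RefSeq annotation of the same build, by symbol.

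The rule for named genes and the 21 gene lists were fixed before the data were examined. The genes named are the 10 highest and 10 lowest ratios among 2047 genes with at least 50 counts in each library, ATF4, and up to 4 members with the most counts per list. A list with at least 5 measured members was described by the percentile of its median among 10000 random lists of the same size. These were drawn within 10 bins of the footprint counts summed over both libraries, or of the area's counts for leaders and coding sequences alone. The same counts form the ratio, and mRNA abundance did not enter. The percentile describes these libraries only. Members of 3 lists were too few: JUN stood for eIF3-regulated mRNAs, MRPL38 (0.02) and DRAP1 (-0.12) for genes with short leaders, and no marker of other cell types reached the minimum. Percentiles for leaders and coding sequences alone, the window from -17 to -15 and the highest position from -25 to -5 at stop codons, and the densities relative to a neighbouring region were chosen after the profiles were seen, as were the windows of 50 nt along ATF4.

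Metagene and ATF4 values were compared between 2 libraries of 80S and 2 of 40S with an exact two-sided permutation test, whose smallest p is 0.333. The labels do not say whether the libraries of a fraction came from separate cultures, so the spread may be technical. The steps were tested on simulated data drawn for the 4175 genes of the eIF3b-bound comparison, with 200 genes changed. Of 50 genes raised by 1 on the log2 scale 84% were beyond counting error, of 50 lowered by 1 80%, of 50 raised by 2 100% and of 50 lowered by 2 98%, against 4.08% of 3975 unchanged genes. Among 20 simulated lists of 18 genes, 0 unchanged lists and 20 lists shifted by 1 fell outside the central 95%. The simulated counts varied by counting noise (Poisson) only, with 1 common ratio for all unchanged genes. The measured log2 ratios ran from -2.08 to 1.98 between the 5th and 95th percentile of genes. These rates therefore describe counting noise alone and do not carry over to the measured genes and lists. Alternatives covered scaling (TMM in edgeR 4.0.16 on R 4.3.3), the prior count, the count minimum, footprint lengths, positions and left-out libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.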

Results

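Footprints of translating and scanning ribosomes were profiled in HEK293T cells, a human embryonic kidney cell line, that had been fixed with 0.3% formaldehyde for 5 min after 48 h of growth. RNase I digestion left the RNA covered by each complex, and the small subunit (40S) and the whole ribosome (80S) were then separated. The series holds 2 unselected 40S libraries, 2 unselected 80S libraries, 1 library of 40S complexes pulled down with an antibody against eIF3b, and 1 mRNA library. eIF3b is a subunit of eIF3, the largest initiation factor, which binds the 40S subunit and takes part in recruiting it to mRNA. Counts per gene were given for the eIF3b-bound library, with 947733 footprints, and for 40S 1, with 834172 footprints. The 5′ ends around start codons numbered 151159 in 40S 1, 69122 in 40S 2, 205451 in 80S 1 and 94512 in 80S 2, and those around stop codons 51176, 13998, 247399 and 166059 in the same order. Comparisons with the eIF3b-bound library had no replicate, so they set 1 library against 1, and their 95% intervals cover counting error only.

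The first comparison asked where on mRNAs the eIF3b-bound 40S complexes lay relative to all 40S complexes. Footprints of the eIF3b-bound library lay mostly in leaders and at start codons, and those of 40S 1 mostly in coding sequences and 3′ UTRs. These are shares of counts and were not scaled to the length of each area. The 5′ UTR took 50.7% of the eIF3b-bound footprints (exact Clopper-Pearson interval 50.6 to 50.8%) and 11% of those of 40S 1 (10.95 to 11.08%), a ratio of 4.60. The start codon area took 18% against 8.52%, a ratio of 2.11. The coding sequence took 17.2% against 31.8%, the stop codon area 0.567% against 1.34%, and the 3′ UTR 13.6% against 47.3%. The medians over genes had the same order with all genes counted. Among 2407 genes with at least 20 leader counts, the median log2 ratio of the leader was 2.27, and 91.8% of these genes were higher in the eIF3b-bound library beyond counting error. The median was 1.22 over 1333 start codon areas, -0.64 over 2734 coding sequences, -1.30 over 156 stop codon areas and -1.53 over 2741 3′ UTRs. Single genes were less uniform outside leaders: 46.5% of the coding sequences were lower beyond counting error and 14.9% higher (60.4% and 8.49% with totals that leave out the 10 genes highest in 40S 1), and 65% of the 3′ UTRs were lower and 12.7% higher. Part of the pooled ratio came from a few genes. The 10 genes highest in 40S 1 held 28.9% of its counts, and the 10 genes highest in the eIF3b-bound library held 7.71% of its own. ARHGAP39 alone gave 106102 of the 394842 3′ UTR counts of 40S 1. Without the 10 genes highest in 40S 1 the leader ratio was 3.33, and the stop codon area, at 0.309, lay below the 3′ UTR, at 0.346. The coding sequence then took 33.7% of the 40S 1 footprints and the 3′ UTR 37.9%. With only leaders and coding sequences counted the leader ratio was 2.90. The reference was 40S 1 alone, which had more 5′ ends past stop codons than 40S 2, with a density of 0.862 against 0.458 relative to the coding sequence.

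**Figure D1:**
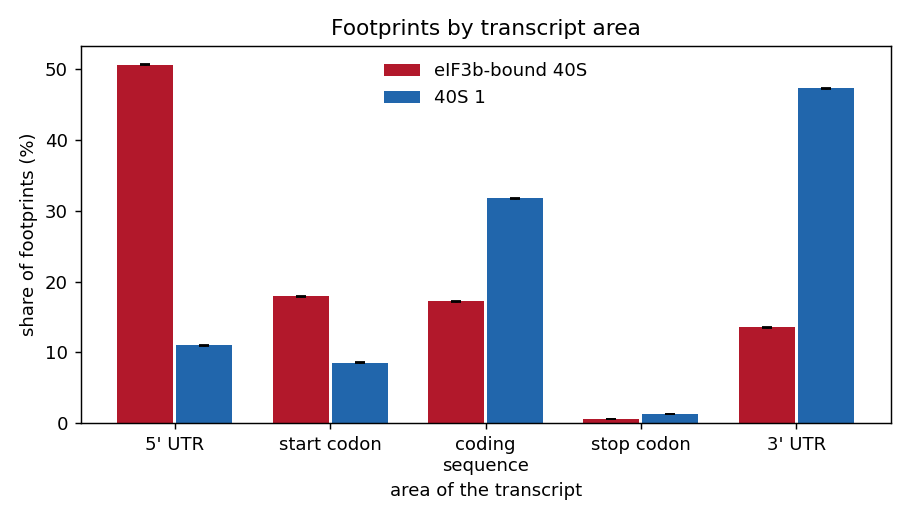
Share of footprints (%) in each area of the transcript for the eIF3b-bound 40S library (red) and 40S 1 (blue), 1 library each; error bars are 95% Clopper-Pearson intervals. The 5′ UTR holds 50.7% of the eIF3b-bound footprints and 11% of those of 40S 1, and the 3′ UTR 13.6% and 47.3%.

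Gene by gene, the mRNAs most over-represented on eIF3b-bound 40S subunits were a mixed set, and those most under-represented were 5 mitochondrially encoded mRNAs and genes with nearly all of their counts in a single area, mostly the 3′ UTR. The median gene had a log2 ratio of 0.25, and directions of genes are read against it, while lists are read against random lists. HPS6, a subunit of a complex needed for lysosome-related organelles, was highest (841 against 74 counts, log2 ratio 3.31, interval 2.98 to 3.69). It lies on chromosome 10 from 102065349 to 102068036 in GRCh38, and 815 of its eIF3b-bound footprints fell in the coding sequence. SDF2L1, an endoplasmic reticulum protein, followed at 2.56, TIMM10, a chaperone of mitochondrial protein import, at 2.49, and KRT10, a keratin, at 2.43. In TIMM10, 79.3% of the eIF3b-bound footprints lay in the leader, while KRT10 had none there. PNMA1 and C1GALT1C1 both had a ratio of 2.27, MYBL2, a cell cycle transcription factor, 2.24, ADISSP 2.22, the linker histone gene H1-10 2.2 and POP7, a subunit of RNase P, 2.19. At the other end, ARHGAP39 had 106113 counts in 40S 1 and 1729 in the eIF3b-bound library, a log2 ratio of -6.12, with 12.7% of all 40S 1 footprints in this gene. The other genes at this end were MT-ATP8 (-5.56), CACTIN (-5.05), ENSG00000256618 (-4.95), MT-ATP6 (-4.94), MIPEP (-4.94), MT-ND5 (-4.83), KDM6B (-4.57), MT-ND4L (-4.53) and MT-CO2 (-4.48). What the 3′ UTR counts of ARHGAP39, CACTIN, ENSG00000256618 and MIPEP came from was not analysed here. Of 4175 genes with at least 20 counts in both libraries together, 761 lay at least 2-fold above the median gene and 926 at least 2-fold below it. Counting intervals excluded the median gene for 1374 genes above it and 1380 below it.

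The 7 mitochondrially encoded mRNAs in the table, which mitochondrial ribosomes translate, were grouped after their values were seen. Together they held 8.70% of 40S 1 and 0.344% of the eIF3b-bound library, and their log2 ratios ran from -5.56 to -3.73.

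Of the gene lists, 4 stood outside the central 95% of 10000 random lists matched on summed footprint counts. These were 4 out of 18 lists with at least 5 measured members, where chance alone gives 0.9. Cytoskeletal genes were high (18 members, median log2 ratio 1.17, percentile 98.2). In this list 14 members lay above the median gene beyond counting error, 1 below it and 3 within it, and PFN1 (1.94), ACTB (1.43), ACTG1 (1.28) and TUBB (0.64) had the most counts. Within areas the list was inside the central 95%, at percentile 18 by leader and 9.26 by coding sequence. Immediate early and similar transcription factors were high too (14 members, median 1.09, percentile 98.7), with 7 above, 1 below and 6 within, and values of 1.83 for JUN, 1.5 for SOX4, 1.2 for ID3 and 0.22 for ID2. This list too lay inside the central 95% within areas, at percentile 66.6 by leader and 73.3 by coding sequence. Ribosomal protein mRNAs were low against random lists of similar footprint counts (34 members, median 0.43, percentile 2.23). Their median still lay above the median gene, with 18 members above it, 12 below it and 4 within counting error. RPLP2 had a ratio of 1.17, RPS12 0.88, RPL13 0.86 and RPL8 0.68. The other mRNAs with a 5′ terminal oligopyrimidine tract were lower still (5 members, median -0.73, percentile 1.06), with EIF4B at -1.02, EEF1G at -0.73, HNRNPA1 at -0.14 and EEF1B2 at 0.86. By coding sequence this list lay inside the central 95%, at percentile 2.79, and its 4 measured leaders were too few for a percentile. Reads of ACTB and ACTG1, of tubulin genes and of ribosomal protein genes can be shared with near-identical copies, so single members are uncertain.

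The other lists lay inside the central 95%. Nuclear genes of oxidative phosphorylation had a median of 0.88 over 37 members (percentile 85.3), with 24 above the median gene beyond counting error, 5 below it and 8 within, ATP5MC3 at 1.83 and UQCRH at 1.55. Among other examples, HSP90AB1, a chaperone, had 0.80, GAPDH and ENO1, glycolytic enzymes, 1.13 and 1.25, and PCNA, a clamp of DNA replication, 1.78. Selenoproteins had a median of 0.96 (8 members, percentile 91.3), cytosolic chaperones 0.76 (17 members, 49.7), hnRNP and SR proteins 0.66 (21 members, 40.3), elongation and termination factors 0.62 (6 members, 51.6), glycolytic enzymes 0.47 (8 members, 23.8) and cell cycle genes 0.43 (20 members, 42.8). Replication-dependent histones had a median of 0.44 (45 members, percentile 11.3), secretory pathway genes 0.22 (23 members, 21.6), proteasome subunits 0.11 (18 members, 9.51) and initiation factors other than eIF3 0.27 (14 members, 16.9). Of the histone genes 21 lay above the median gene, 12 below it and 12 within counting error, with H2AC6 at 1.74, H4C14 at 0.58 and H4C3 at 0.01. The initiation factors split evenly, with 6 above, 6 below and 2 within, from EIF1AX at 1.75 and EIF5 at 0.91 to EIF4H at -1.36. The eIF3 subunits had a median of 0.23 (7 members, percentile 17.8), with 5 within counting error of the median gene and 2 below it. Stress-response mRNAs with upstream open reading frames had a median of 0.69 (10 members, percentile 79.6), from AZIN1 at 0.85 and ATF4 at 0.67 to EPRS1 at -0.35 and IBTK at -1.53. Histone genes, and the pair HSPA1A (1.79) and HSPA1B (1.51), are near-identical copies whose reads the counting could split. None of the 7 marker genes of other cell types in the table reached 20 counts.

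**Figure D2:**
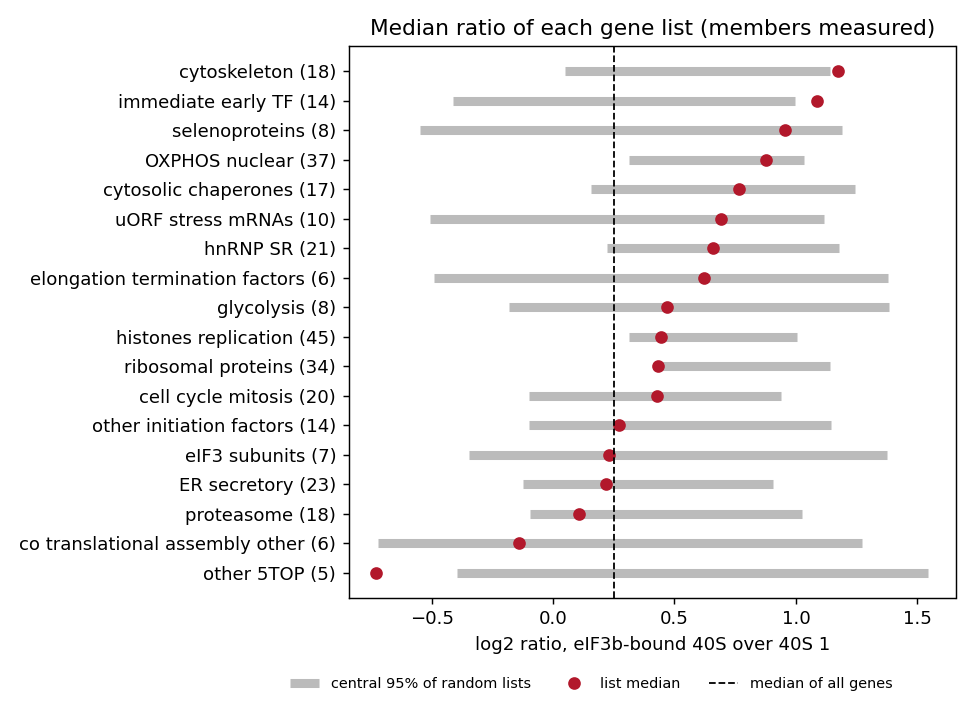
Median log2 ratio of CPM, eIF3b-bound 40S over 40S 1 (x axis), for each gene list with its number of measured members (y axis). Grey bars span the central 95% of 10000 random lists matched on summed footprint counts, and the dashed line is the median of all genes at 0.25. Cytoskeletal genes (1.17) and immediate early factors (1.09) lie above their bars, and ribosomal protein genes (0.43) and other oligopyrimidine-tract mRNAs (-0.73) below theirs.

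The series title names assembly of initiation factor complexes during translation as a question, so the coding sequences of the eIF3 subunits were compared. The pull-down library held 40S complexes, and the series has no pull-down library of whole ribosomes, which do the translating. The values for the subunits and for other reported targets therefore cannot decide, in either direction, whether such assembly occurs. They describe only how eIF3b-bound 40S footprints compared with those of 40S 1. EIF3B, which encodes the pulled-down subunit, had 248 coding sequence footprints in the eIF3b-bound library and 157 in 40S 1, a log2 ratio of 0.47 (interval 0.18 to 0.77), against a median of -0.64 over all coding sequences. EIF3I had -0.21 (interval -0.52 to 0.10) and EIF3A, another core subunit, -2.94 (-3.65 to -2.34). EIF3M had -0.67, EIF3G -0.78, EIF3H -0.78 and EIF3C, which has a near-identical copy, -1.14. Against that median, EIF3B and EIF3I lay above beyond counting error, EIF3A and EIF3C below, and the other 3 within it. Such calls were common over whole genes, where 1374 of 4175 lay above the median gene beyond counting error and 1380 below it. How many coding sequences lay beyond their own median was not counted. The quartiles over all coding sequences were -1.49 and 0.26. EIF3B lay above the upper quartile, EIF3A below the lower one, and EIF3I and EIF3C between them. As a list, the 7 measured subunits had a coding sequence median of -0.78 at percentile 27.8 of random lists, inside the central 95%. Their leaders had a median of 3.21 over 5 members, at percentile 97.6, outside the central 95%, and at percentile 97.35, inside it, with a minimum of 50 counts per gene. Other reported targets of assembly during translation had a median of -0.14 over all areas (6 members, percentile 14.4) and of -1.45 in the coding sequence (5 members, percentile 5.35).

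Around start codons the next comparison asked how 80S footprints were placed relative to 40S footprints. In 40S libraries most 5′ ends lay upstream of the start codon, and in 80S libraries most lay near or downstream of it. From position -80 to -15 lay 57.4% ± 2.07 (SD, n = 2) of the 40S 5′ ends and 29.7% ± 4.60 (SD, n = 2) of the 80S 5′ ends. From +1 to +30 lay 20.0% ± 0.469 (SD, n = 2) and 45.3% ± 2.03 (SD, n = 2). The first window is wider than the second, so these shares are not densities. Per position, the density from +1 to +30 was 0.982 and 0.984 times that from -80 to -41 in 40S 1 and 40S 2. In 80S 1 and 80S 2 it was 4.22 and 5.76 times. Per position, 40S 5′ ends were therefore about as dense past the start codon as far upstream of it. The downstream difference was 25.4 percentage points, 23.6 between the number 1 libraries and 27.1 between the number 2 libraries, so it exceeded the spread between replicates. The exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow. Both fractions had a peak from -14 to -12, the place of complexes that had found the start codon, with 6.84% ± 0.554 (SD, n = 2) of the 40S and 6.37% ± 1.5 (SD, n = 2) of the 80S 5′ ends, a difference within the spread between replicates (exact permutation p = 1). Its highest position was -13 in both number 1 libraries and -12 in both number 2 libraries. Measured against the density from -80 to -41, this peak was 3.12 and 3.62 times as high in 40S 1 and 40S 2, and 5.10 and 9.14 times in 80S 1 and 80S 2. Every one of the 4 libraries also had a narrow peak at position 0.

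**Figure D3:**
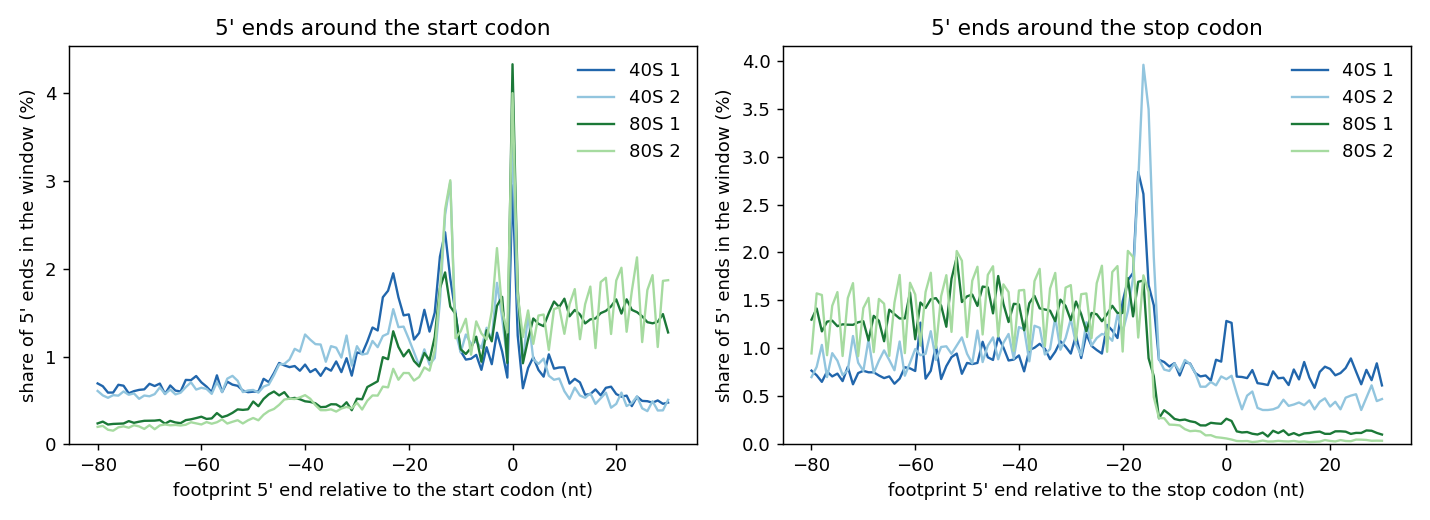
Share of 5′ ends (%) at each position around the start codon (left) and the stop codon (right), in nt, for 40S 1, 40S 2, 80S 1 and 80S 2, summed over genes. The 80S lines stay high downstream of the start codon and drop after the stop codon, while the 40S lines peak just before the stop codon and continue past it.

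Around stop codons, 40S libraries had a sharp peak, and 80S libraries had none of that height. The density of 5′ ends from -17 to -15 was 2.70 times that of the coding sequence in 40S 1 and 3.41 times in 40S 2, against 1.03 times in both 80S 1 and 80S 2. The 40S mean of 3.06 ± 0.502 (SD, n = 2) and the 80S mean of 1.03 ± 0.00346 (SD, n = 2) differed by more than the spread between replicates (exact two-sided permutation p = 0.333, the smallest possible). From -25 to -5 the highest position was -17 in 40S 1, -16 in 40S 2 and -19 in both 80S libraries, and its count was 3.24, 3.97, 1.25 and 1.39 times the mean of the coding sequence in 40S 1, 40S 2, 80S 1 and 80S 2. Past the stop codon, from 0 to +30, lay 23.4% of the 5′ ends of 40S 1 and 14.1% of 40S 2, against 3.97% of 80S 1 and 1.08% of 80S 2. Relative to the density in the coding sequence, 40S footprints there stood at 0.660 ± 0.286 (SD, n = 2) and 80S footprints at 0.0581 ± 0.0481 (SD, n = 2).

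Reading frame preference was weak, and downstream of the start codon the fullest frame was the same in both fractions of a library number. In 80S 2 the 3 frames downstream of the start codon held 38.4%, 26.3% and 35.3% of the 5′ ends, and upstream of the stop codon 39.2%, 23.4% and 37.4%. Upstream of the stop codon they held 38.1%, 29.5% and 32.4% in 40S 2, 31.8%, 35.7% and 32.5% in 40S 1, and 30.6%, 34.65% and 34.72% in 80S 1. There the number 2 libraries shared their fullest frame, and the number 1 libraries did not. In 80S 1 the frames held 32.4%, 35% and 32.6% downstream of the start codon. In 40S 1 they held 32.1%, 37.8% and 30.1%, and in 40S 2 36.4%, 33.8% and 29.8%. The share of the fullest frame was 37.1% ± 0.967 (SD, n = 2) in 40S and 36.7% ± 2.44 (SD, n = 2) in 80S, a difference within the spread between replicates (exact permutation p = 1).

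Footprints around start codons were longer in the number 1 libraries. At the start codon the median length was 37 nt in both 40S 1 and 80S 1, 32 nt in 40S 2 and 33 nt in 80S 2. Far upstream of the start codon, from -80 to -41, medians rose to 44 nt in 40S 1, 46 nt in 80S 1 and 37 nt in both number 2 libraries. At stop codons the most frequent length was 34 nt in both number 1 libraries and 31 nt in both number 2 libraries. Past them the most frequent length was close in the 40S libraries, with 26 nt in 40S 1 and 27 nt in 40S 2. It was 25 nt in 80S 1 and 31 nt in 80S 2, which had 1.08% of its 5′ ends there. Lengths rest on a first length column of 18 nt inferred from the 40S libraries and not checked for 80S. Absolute values could therefore be off, by an amount that was not estimated. The authors' deposited per-gene means, for footprints that begin 12 to 14 nt before the start codon, put the most frequent 3′ end at +21 in 40S 1, with 8.84% of 3′ ends, and at +17 in 40S 2, with 12.5%. The deposited 95 percentile intervals of the libraries did not overlap at 15 of 48 positions where 40S 1 was higher and at 13 where 40S 2 was higher.

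Coverage around annotated transcript 5′ ends rose steeply at the cap in all 4 libraries of that file. Coverage at the annotated end itself was 30.3% of its maximum in the eIF3b-bound library, 36.7% in 40S 1, 33.3% in 40S 2 and 27.3% in the mRNA library. It peaked at +27 in the eIF3b-bound library, +30 in 40S 1 and +31 in 40S 2 and the mRNA library, and at +40 it was still 93.9%, 94.7%, 93.9% and 95% of the maximum. Upstream of the annotated end lay 5.28% of the coverage in the eIF3b-bound library, 4.98% in 40S 1, 5.07% in 40S 2 and 2.48% in the mRNA library. The peak of the eIF3b-bound library, at 45527, was 2.68 times that of 40S 1 in deposited units, which show no scaling for depth, and 1.03 times when each was taken as a share of its window total.

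ATF4, a stress-response transcription factor whose leader holds upstream open reading frames, was deposited position by position. It lies on chromosome 22 from 39520559 to 39522686 in GRCh38. The eIF3b-bound and 40S footprints crowded at the 5′ end of its leader, while 80S footprints spread further along the transcript. The first 50 nt held 45.1% of the coverage in the eIF3b-bound library, 43.7% ± 8.45 (SD, n = 2) in 40S and 18.7% ± 2.36 (SD, n = 2) in 80S. From +51 to +100 the eIF3b-bound library had 25.3%, 40S 12.7% ± 2.64 (SD, n = 2) and 80S 8.53% ± 0.299 (SD, n = 2). From +301 to +350 the order was the other way round, with 0.418% in the eIF3b-bound library, 1.4% ± 0.225 (SD, n = 2) in 40S and 6.70% ± 1.15 (SD, n = 2) in 80S. The 80S and 40S libraries did not overlap in these 3 windows, and the exact permutation p was 0.333 in each, the smallest possible. Beyond +350 lay 5.56% in the eIF3b-bound library, 33.8% in 40S 1, 11.2% in 40S 2, 41.1% in 80S 1 and 38.4% in 80S 2. In the table of counts ATF4 had 2684 footprints in the eIF3b-bound library and 1484 in 40S 1, 0.42 above the median gene on the log2 scale, with 92.5% and 60.4% of them in the leader.

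**Figure D4:**
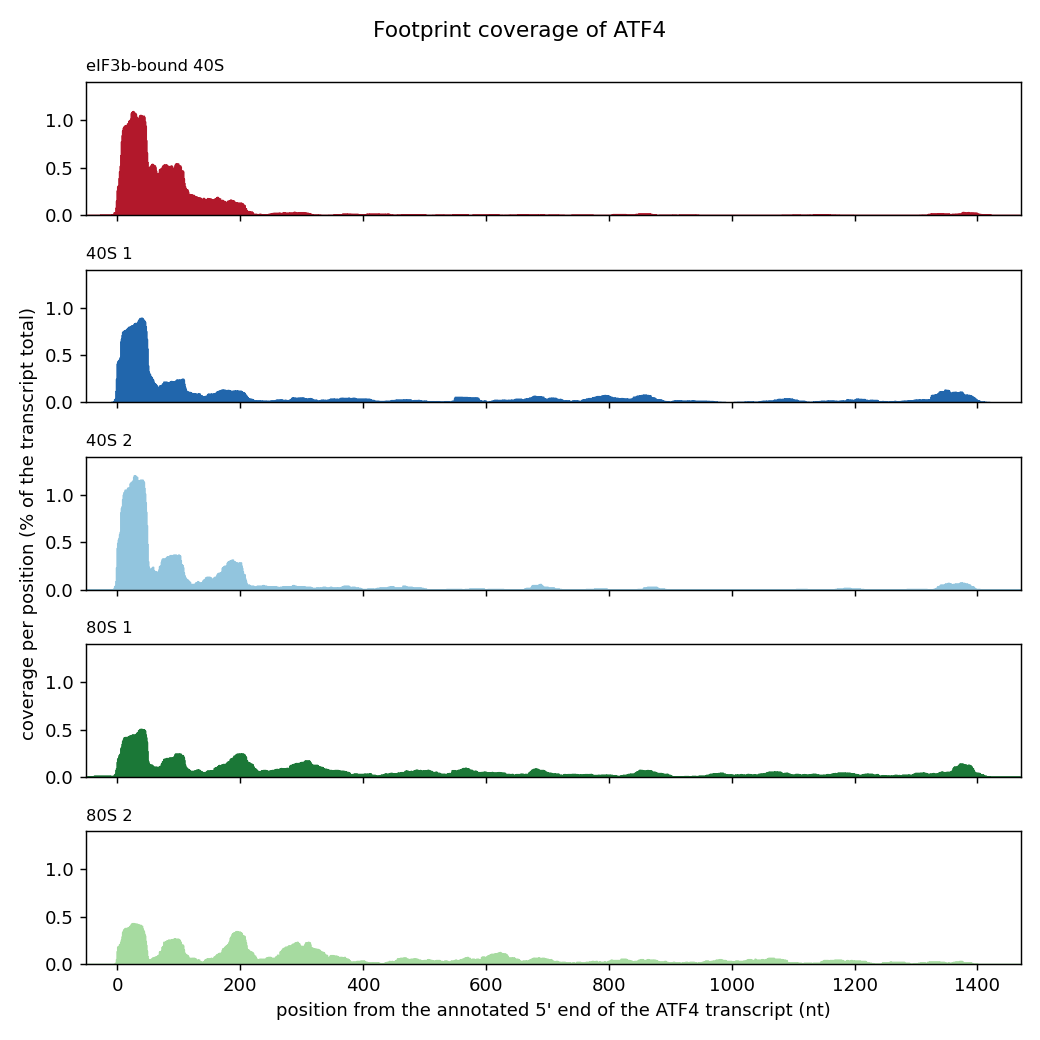
Coverage of the ATF4 transcript at each position from its annotated 5′ end (x axis, nt), as a percentage of the library's total on this transcript (y axis), for the eIF3b-bound 40S, 40S 1, 40S 2, 80S 1 and 80S 2 libraries. The first 50 nt hold 45.1% of the eIF3b-bound coverage, 37.7% and 49.7% in 40S 1 and 40S 2, and 20.4% and 17.1% in 80S 1 and 80S 2.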

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

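Of 59 alternatives, 5 turned a sign and 10 moved a value. The other 44 did neither, among them the pairings by number, which could not change a value. They were judged by sign alone for differences between 80S and 40S and within 1.5 times for counts. The leader ratio counted as moved outside its counting interval. The leader ratio of 4.60 was 2.90 with leaders and coding sequences only, 5.49 as the ratio of the medians over genes, 3.33 without the 10 genes highest in 40S 1 and 4.21 without mitochondrial mRNAs, the last chosen after seeing the data. The median gene ratio of 0.25 became -7.01e-05 with TMM and -0.22 with totals that leave out the 10 genes, also chosen after seeing the data. Whole genes were read against that median, and lists against random lists. Counts per area were read against 0 and depend on the scaling, as checked after seeing the data. With TMM, 2119 leaders and 288 coding sequences were higher and 36 start codon areas lower. With totals that leave out the 10 genes, 2031 leaders, 232 coding sequences, 234 3′ UTRs and 4 stop codon areas were higher and 52 start codon areas lower, where the unaltered totals gave 2209, 407, 347, 8 and 23. The area medians kept their sign under both. With a prior count of 2, 720 genes were at least 2-fold higher and 897 lower, and with a minimum of 50 counts 544 and 724 of 3362. The same 4 lists stood apart at that minimum. As shares of the window total, the cap peak ratio fell from 2.68 to 1.03. As a share of the transcript total, the ATF4 log2 ratio over the first 50 nt fell from 0.87 to 0.26. Both fell because the totals were themselves higher in the eIF3b-bound library than in 40S 1. Mean cap coverage from +1 to +40 was 37990 against 14642, and total ATF4 coverage 94252 against 61634. Why the totals were higher was not tested.

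The downstream difference at start codons and the peak difference at stop codons kept their direction in every alternative run, from 20.6 to 29.4 percentage points and from -2.49 to -1.67, the stop codon value without position -16 (-1.92) being chosen after seeing the data. The frame difference of -0.397 points became 1.29 with lengths of 25 to 35 nt and ran from -2.12 to 1.33 when a library was left out. The cause was not tested. Pairing by number (replicate block) leaves these differences at 25.4, -2.03 and -0.397 by arithmetic, so it could not test their size or sign. Its exact sign-flip p was 0.5, 0.5 and 1, where 0.5 is the smallest that 2 pairs allow. Area shares, with 1 library on each side, had none to leave out. Not run were all alternatives of the gene and list tests of 80S against 40S and of ribosome load, 40S replicate 2 as control, the pooled edgeR fit, the stop codon peak without the 3 nt around it, which leaves no window, and ATF4 without its start and stop codons, whose positions were not used here. At this depth 156 stop codon areas reached 20 counts.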

Other observations

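Against the general pattern, 407 coding sequences and 347 3′ UTRs were higher in the eIF3b-bound library than in 40S 1 beyond counting error (232 and 234 with totals that leave out the 10 genes highest in 40S 1); the genes highest in each area were ranked after the data were seen. Among 539 coding sequences with at least 50 counts in each library, whose median log2 ratio was -0.35, HPS6 stood at 3.31, KRT10 at 2.58, GTPBP3, an enzyme of mitochondrial tRNA modification, at 2.45, JMJD4 at 2.16, TMEM160 at 2.11 and the histone gene H3C7 at 1.66. Among 367 3′ UTRs, with a median of -0.81, ACTG1 stood at 2.45, ENSG00000203812 at 2.44, H4C15 at 2.30, H4C8 at 2.26, ATP5ME, a subunit of ATP synthase, at 2.21 and C1GALT1C1 at 2.2. Histone genes can share reads with near-identical copies.

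By coding sequence alone, replication-dependent histones were high (45 members, median -0.10, percentile 98.5 of random lists), and ribosomal proteins (median -1.09, percentile 0.33), hnRNP and SR proteins (median -1.30, percentile 0.34) and cell cycle genes (median -1.36, percentile 0.56) were low. By leader alone, ribosomal proteins (median 1.81, percentile 0) and nuclear genes of oxidative phosphorylation (median 1.99, percentile 0.785) were low against random lists of similar leader counts. The eIF3 subunits (median 3.21, percentile 97.6) were high, though inside the central 95% with a minimum of 50 counts (percentile 97.35).

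For the 3 patterns that follow, every test was chosen after the result was seen. The first is the low level of mitochondrial mRNAs in the eIF3b-bound library. A few genes taking most of the eIF3b-bound counts did not account for it, since the 10 highest held 7.71% of that library and would have needed 91.4% to lower a median log2 ratio from -1 to -4.53. For a general loss of coding sequence footprints, 2727 nuclear genes had a median coding sequence ratio of -0.64, against a mitochondrial median of -4.52. Of these nuclear genes 1.91% (52) were as low as the mitochondrial median. The mitochondrial mRNAs were grouped after they were seen to be low, so a small share was given in advance and excludes nothing. Mitochondrial ribosomes that sediment with the 40S fraction and do not bind eIF3b may be a source, as a hypothesis that these files do not test. With 1 library on each side, a difference between these libraries stays open.

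The second is the peak at position 0, which was 2.95 and 2.71 times the mean of its neighbours in 40S 1 and 40S 2 and 3.22 and 2.68 times in 80S 1 and 80S 2. Its height relative to its neighbours differed by 1.2 times between the highest and lowest library. An end preference of digestion or cloning shared by all libraries could give such similar heights. 80S ribosomes early in the coding sequence would raise position 0 in 80S, but could raise its neighbours too. The mean fold over the neighbours, 1.04 times that of 40S, therefore cannot decide on this explanation. As a share of the 5′ ends around start codons, position 0 held 4.33% in 80S 1 and 4.004% in 80S 2. It held 2.95% in 40S 1 and 3.48% in 40S 2, so by share both 80S libraries were higher. Mitochondrial mRNAs, which have almost no leader, could place 5′ ends there: the 1499 start area counts of the 7 in the table equal 50.8% of the excess in 40S 1. Most of these counts, 1288, came from MT-CO1 alone, and MT-CO2, MT-ND5 and MT-ND4L had 0. Other mitochondrial mRNAs are not analysed here, so this cannot be told apart. No biological explanation from the design was tested.

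The third is the longer footprints of the number 1 libraries at start codons. Past stop codons their most frequent lengths were not longer. Median lengths at the start codon were longer by 5 nt in 40S and by 4 nt in 80S, but these differences prompted the question of a library batch and do not test it. Length columns that start at another length were excluded for 40S, where the best first lengths differed by 0 nt, and were not checked for 80S. The read layout, and any difference in library batch or digestion between the numbers, may each lie behind the 5 nt and 4 nt, so they cannot be told apart.

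One hypothesis was written before its result was seen: that mRNAs recovered more in the selected library would gain in leader and coding sequence alike. Across 1767 genes with at least 20 counts in each area, Spearman's rho was -0.029 (permutation p = 0.224) and Pearson's r -0.0437 (permutation p = 0.0667), across genes, which are not independent replicates. Leader and coding sequence counts do not overlap, so the result argues against recovery acting on whole mRNAs as the main order of both ratios.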
